A study of Rattus norvegicus with 6 samples.

How the data were processed

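RNA sequencing data of 6 libraries were used, 3 from rat trophoblast stem cells and 3 from such cells differentiated for 8 days, as the samples' titles and the series' design text give them. The labels' time point reads day 8 for the stem libraries too, so the groups were taken from the titles. Nothing in the labels says whether libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

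The authors deposited 1 table with RPKM values, per the file headers from paired reads, for 28068 transcript rows in each library. The genome build was Rnor 5.0, per the submitters' processing notes; the aligner and counting program are not given in the sources used here. The same deposited table holds the authors' fold changes, t-test p-values and FDR-corrected p-values, which were not used as main results. Recomputing a t-test on untransformed RPKM gave the deposited p-value in all 20621 rows with a value, within 1e-06. An FDR under 0.05 stood beside 8767 rows in the authors' deposited values, 3145 higher and 5622 lower in differentiated cells, and 7434 (85.4%) of the calls made here were among them. A row named for the same gene more than once was treated as a separate transcript, and its symbol was the row name without the trailing number. The table has 23984 symbols, of which 16027 matched symbols and 2082 matched synonyms in a RefSeq gene list of the later assembly GRCr8, which was used only to count matches. No coordinates are given, since the builds differ.

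Whole reads were worked out from the RPKM steps and the transcript lengths, and all 105332 values above 0 came out whole within 0.001 reads (100%). On simulated tables the procedure recovered 6 of 6 library totals and 99.2% of rows exactly. These reads served for depth, for shares of reads, for random thinning, for a test with voom weights, and for library totals without mitochondrially encoded reads, without the 100 most abundant rows or from reads in rows only. They also served for the ratios between rows of 1 symbol. Reads in rows were 73.9% ± 0.119 of totals in differentiated and 77.8% ± 1.04 in stem libraries. Counting error matters below about 3 reads, which is 0.115 to 0.138 RPKM in a transcript of 1 kilobase and less in a longer one. Differences between replicates exceeded sampling noise in every pair (mean chi-square of 3.41 to 28.4 per row), so no pair was treated as a duplicate.

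The comparison was planned for raw counts, and since the table holds RPKM the planned fallback was used. It was limma-trend with robust variance (R 4.3.3, limma 3.58.1) on log2(RPKM + 0.5), over rows with at least 1 RPKM in at least 3 libraries, all 6 libraries in 1 fit with no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 28068 rows, 11293 passed the filter (10475 symbols). On data simulated with the same means, 200 of 11293 rows were changed in each of 10 draws. Recovered were 100% of rows changed by -2, 97.8% by -1, 98.5% by 1, 79.8% by -0.5 and 81% by 0.5 (log2). Of the calls, 6.54% were false, above the nominal rate. The simulation gave all rows 1 dispersion and had no outlying library. In the real fit 77.1% of rows passed, so these rates do not carry over to it. Gene lists (17, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with estimated correlations and fry as alternatives, and Benjamini-Hochberg adjustment over the lists. On simulated data camera found the 1 changed list of 17 and called no unchanged list. The simulated rows were drawn independently, so this did not test the preset correlation for lists whose members vary together. For a symbol with several rows, the row with the highest total stood for it in a list and as a named gene. Values of such a gene are therefore those of 1 transcript row. Shares of the prolactin family and of the 10 most abundant rows were compared with exact permutation tests.

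Named genes were fixed by a rule before the data were examined. They were the 6 largest rises and the 6 largest falls past the threshold with non-overlapping groups and a mean of at least 10 RPKM in the higher group, up to 2 members per list, and Tfpi, F3, Thbd, Serpine1, Plat, Cdx2, Eomes, Prl3b1, Mmp9 and Mki67.

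Alternatives fixed before the data were examined were other scalings, filters, pseudocounts of 0.1 and 1, thinned reads, voom weights on the worked-out reads, a replicate block, a test against a fold of 1.2, a threshold of 0.01 and leaving out each library. Added after seeing the data were a block for the sequencing lane in the column headers, RPKM summed per symbol, totals without mitochondrially encoded reads, and shares of reads. When 1 library was left out, the fit first used the low-value filter at 3 of the remaining 5 libraries, as fixed beforehand, which dropped rows present only in the shortened group. After these results were seen, the fits were repeated on the rows of the fit to all 6 libraries and with a filter at 2 of the 5, both added afterwards. Values without 1 library are on the rows of the fit to all 6 unless the filter is named. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

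Gene groups were also chosen after seeing the data, for description only, so no test of a group is given for them: the carcinoembryonic antigen and pregnancy-specific glycoprotein family, clade B serpins, cathepsins, cytosolic ribosomal proteins, mitochondrially encoded proteins, heat shock proteins, epithelial junctions, immediate early genes, and DNA methylation and germline-like genes. The ribosomal and heat shock groups were first taken by symbol prefix, and were then limited to the named proteins, leaving out kinases, binding proteins, pseudogenes and other genes that share the prefix.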

Results

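Messenger RNA was profiled by sequencing in rat trophoblast stem cells, the placental precursor cells of the blastocyst's outer layer, and in the same kind of cells after 8 days of differentiation towards extravillous trophoblast, the invasive placental lineage that remodels maternal vessels. There were 3 stem and 3 differentiated libraries. Expression was given as RPKM (reads per kilobase of transcript, scaled to the library's read total). Each value below is a mean RPKM ± SD over n = 3 libraries per group, and each log2 fold change is differentiated minus stem on log2(RPKM + 0.5), which understates changes of low genes. Library totals worked out from the RPKM steps ran from 21792208 to 22948524 reads in stem and from 23560356 to 26059487 reads in differentiated libraries, so a single read in a transcript of 1 kilobase was worth 0.0384 to 0.0459 RPKM. The series' title names the pathways of hemostasis and of hemochorial placentation, and the comparison asks how expression of such genes differs between the 2 states.

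Most of the tested transcript rows differed between differentiated and stem cells, and the largest changes come first. Ceacam15, of the carcinoembryonic antigen family, rose from 6.02 ± 0.614 to 635 ± 93.6 RPKM, and Adm, which encodes the vasodilator peptide adrenomedullin, rose from 4.58 ± 0.215 to 257 ± 36.5. Prl5a1 and Prl8a9, of the placental prolactin family, rose from 1.07 ± 0.208 to 77.9 ± 11.8 and from 0.330 ± 0.0738 to 32.8 ± 8.75 RPKM. Prl8a9 has 2 rows, and the row with the higher total is given. Its log2 fold change was 5.29, and its ratio to the other row rose by 3.90 (log2, limma, adjusted p = 0.000479), so the other row rose less. The serpin Serpinb9d rose from 1.10 ± 0.348 to 59.7 ± 6.30, and Nptx1, which encodes a neuronal pentraxin, rose from 0.0703 ± 0.0702 to 17.8 ± 1.45. In the other direction, Ooep, known from the oocyte, fell from 27.9 ± 1.21 to 0.0525 ± 0.0456 RPKM, and Dnmt3l, a cofactor of de novo DNA methylation, from 20.1 ± 1.83 to 0.111 ± 0.0593. Prg2 fell from 21.8 ± 0.624 to 0.0321 ± 0.0557, Ddah1, which breaks down an inhibitor of nitric oxide synthase, from 23.7 ± 1.88 to 0.0843 ± 0.0273, and Mapt, which encodes the microtubule protein tau, from 32.6 ± 5.25 to 0.619 ± 0.148. The imprinted gene Phlda2 fell from 239 ± 12.1 to 7.19 ± 1.02 RPKM. These were the 6 largest rises and the 6 largest falls under the naming rule, with log2 fold changes from 5.01 to 6.60 and from -5.69 to -4.88.

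Of 11293 transcript rows tested, 8709 (77.1%) passed an adjusted p of 0.05 in limma-trend, 2761 of them higher and 5948 lower in differentiated cells. Of these, 3596 differed by at least 2-fold, 1200 higher and 2396 lower. The median tested row lay at a log2 fold change of -0.33, and at 0.01 after the libraries were scaled by median-of-ratios factors, whose mean log2 in differentiated minus stem libraries was -0.38. After that scaling the calls split as 4219 higher and 4202 lower (50.1% higher, against 31.7% before). At 2-fold 1800 rows were higher and 1378 lower. Such scaling assumes that the median row is unchanged and so sets it near 0. The even split follows from that assumption and is not a separate result. In 9079 rows (80.4%) the values of the groups did not overlap, where chance gives 10%. Stem replicate 3 stood apart from the other stem libraries on the component of variation that took 4.22% of the variance, and 275 rows lay over 2-fold below both other stem libraries there. Without it, 8991 of the same rows changed, 2941 higher and 6050 lower, with 1197 higher and 2338 lower by at least 2-fold. With the low-value filter applied to the other 5 libraries, 8462 of 10744 rows changed, 2929 higher and 5533 lower.

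**Figure D1:**
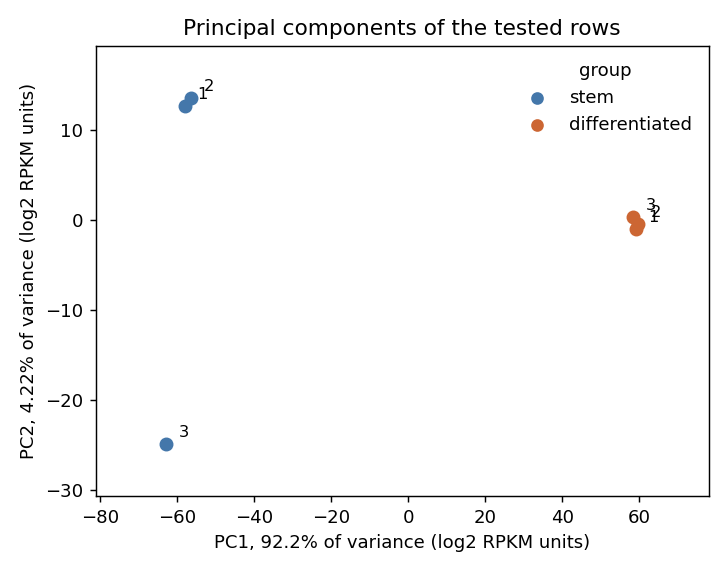
Each point is a library, placed by the first (x axis) and second (y axis) principal component of log2(RPKM + 0.5) over the tested rows, with colours for the groups and digits for replicate numbers. The groups lie apart on the first component, with 92.2% of the variance, and stem replicate 3 lies apart from the other stem libraries on the second, with 4.22%.

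Genes of hemostasis changed in both directions, and Tfpi reached the highest level of the tested members in differentiated cells. Tfpi encodes tissue factor pathway inhibitor, the main brake on the start of coagulation. Its longer row rose 11.2-fold, from 274 ± 23.9 to 3064 ± 137 RPKM (log2 fold change 3.48, SE 0.072, limma adjusted p = 2.94e-09). Thbd, the thrombin receptor that turns thrombin towards anticoagulation, rose from 0.121 ± 0.0665 to 18.7 ± 2.79 (log2 fold change 4.94, SE 0.14, adjusted p = 1.17e-08). Serpine1, which encodes plasminogen activator inhibitor 1, rose 10.7-fold, from 54.5 ± 3.83 to 582 ± 48.5, and F3, which encodes tissue factor itself, rose 1.88-fold, from 15.1 ± 0.417 to 28.3 ± 2.88. Plat, which encodes tissue plasminogen activator, did not pass the test (39.5 ± 2.14 against 40.4 ± 4.48, log2 fold change 0.03, adjusted p = 0.778), but passed as higher after median-of-ratios scaling (0.40, adjusted p = 0.00365). Of 13 tested coagulation and fibrinolysis genes, 9 rose, 3 fell (Pros1, S100a10 and Serpine2, named after their values were seen) and 1, Plat, did not pass. The list moved up against the other rows (camera adjusted p = 0.000969), and had an adjusted p = 0.109 with an estimated correlation. That correlation was -0.05, under the preset 0.01, so correlated members do not account for the lost call.

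**Figure D2:**
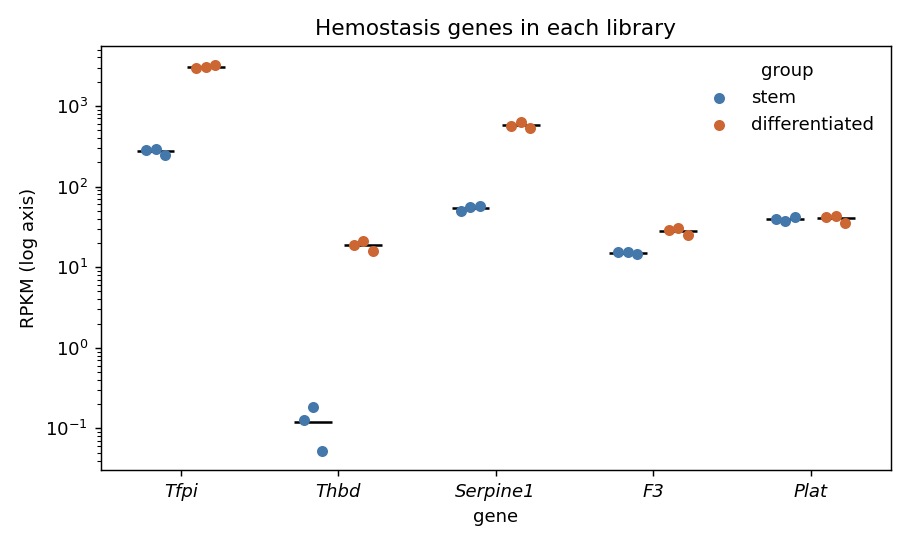
Points are the RPKM (log y axis) of 5 hemostasis genes (x axis) in each of 3 stem and 3 differentiated libraries, and horizontal lines are group means. Tfpi, Thbd, Serpine1 and F3 lie higher in all 3 differentiated libraries than in any stem library, and Plat overlaps between groups at means of 39.5 and 40.4 RPKM.

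Genes of thrombin receptors and platelet function also changed in both directions. Ptgis, which makes the platelet inhibitor prostacyclin, rose from 2.48 ± 0.282 to 11.6 ± 1.59 RPKM, and Nt5e, which makes adenosine, from 0.277 ± 0.0384 to 2.49 ± 0.165. Of 10 tested members 6 rose, 3 fell (F2rl1, Cd9 and F2r, named after their values were seen) and 1, Itga2, did not pass. The list moved up (camera adjusted p = 0.0312). With an estimated correlation (0.00721, under the preset 0.01) the adjusted p was 0.246, and after median-of-ratios scaling it was 0.123. With at least 10 CPM in 3 libraries it was 0.194. With 1 library left out and the filter applied to the other 5, the call was lost in 5 of 6 fits (all but the fit without stem replicate 2), at up to 0.157. That filter drops rows present only in the shortened group. On the rows of the fit to all 6 libraries, no fit that left out 1 library lost the call. After scaling, 7 members were higher and 3 lower.

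Genes of differentiated trophoblast rose together. Of 22 tested members of the giant and invasive cell list, 20 rose, Ascl2 fell and Cts7 did not pass (both named after their values were seen). The matrix metalloprotease genes Mmp12 and Mmp9 rose from 0.621 ± 0.106 to 29.6 ± 8.42 and from 27.8 ± 1.17 to 179 ± 4.54 RPKM. Prl5a1 is given above, and Prl3b1, a placental lactogen, rose 7.24-fold, from 2.28 ± 0.562 to 16.5 ± 2.42. The list moved up with a camera adjusted p of 1.57e-11, and was the only 1 of 17 lists past the threshold with an estimated correlation, at an adjusted p = 0.024. Of its 22 tested members 12 are also in other lists, 5 of them in the prolactin family, so its result and that family's overlap. All 15 tested members of the prolactin family rose (camera adjusted p = 1.51e-10, adjusted p = 0.0954 with an estimated correlation). Members of this family resemble each other closely, so reads could be split between copies and single values are uncertain. The family made up 0.0771% ± 0.0105 of summed RPKM in stem and 0.648% ± 0.0339 in differentiated libraries (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). As a share of reads it made up 0.0464% ± 0.00618 and 0.384% ± 0.0189. The 10 most abundant rows took 10.8% ± 0.349 and 9.92% ± 0.091 of summed RPKM (exact two-sided permutation p = 0.1).

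Genes of the stem state mostly fell. Esrrb and Id2, transcription regulators of the stem state, fell from 20.6 ± 2.14 to 0.309 ± 0.0465 and from 135 ± 11.5 to 6.28 ± 1.17 RPKM. Cdx2, which specifies trophectoderm, fell 2.46-fold, from 32.6 ± 0.668 to 13.3 ± 0.939. Eomes, another stem-state factor, fell from 83.4 ± 8.70 to 55.7 ± 6.32 (log2 fold change -0.58, adjusted p = 0.00101), but did not pass after scaling (-0.20, adjusted p = 0.11). Of 12 tested members 10 fell and 2 rose, Tfap2c and Ets2 (named after their values were seen). The list moved down at an adjusted p of 0.0477, close to the threshold, and had an adjusted p = 0.386 with an estimated correlation. On the same rows, leaving out stem replicate 2 gave 0.0538 and leaving out stem replicate 3 gave 0.0603, and with the filter applied to the other 5 libraries the call was lost in all 6 fits that left out 1 library (0.0646 to 0.0905). A filter at 10 CPM and voom weights also ended the call, while median-of-ratios scaling gave 0.0119, with 9 members lower and 2 higher. With fry, which tests a list on its own, the adjusted p was 1.82e-05. Most tested rows changed, so passing fry says little about this list.

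Cell-cycle genes fell as groups. Plk1, a mitotic kinase, fell 10.4-fold, from 72.5 ± 4.89 to 6.98 ± 0.182 RPKM, and Bub1b, of the spindle checkpoint, 9.10-fold, from 36.9 ± 2.35 to 4.05 ± 0.418. Of 25 tested mitotic genes 22 fell and 3, Ttk, Cenpf and Cenpe (named after their values were seen), did not pass (camera adjusted p = 2.97e-05, adjusted p = 0.246 with an estimated correlation). Without stem replicate 3 all 25 fell, with log2 fold changes of -1.20 for Ttk, -1.66 for Cenpf and -0.31 for Cenpe, which had 0.46 with all libraries. Of 26 DNA replication genes 23 fell and 3, E2f1, Gins2 and Ccne2 (also named afterwards), did not pass (camera adjusted p = 6.25e-05, adjusted p = 0.246 with an estimated correlation). Without stem replicate 3, Ccne2 passed as higher (log2 fold change 0.50, adjusted p = 0.00013, against 1.27 and adjusted p = 0.162 with all libraries). Ccne1, a cyclin of S-phase entry, fell from 115 ± 6.60 to 16.7 ± 0.938, and Orc1, of the replication origin, from 30.02 ± 1.55 to 6.47 ± 0.744. Mki67, a proliferation marker, had 47.7 ± 26.5 RPKM in stem and 6.69 ± 0.0504 in differentiated libraries, and 17.1 RPKM in stem replicate 3 against 60.9 and 64.9 in the other stem libraries. Its log2 fold change was -2.52 (adjusted p = 0.011), and -3.14 without stem replicate 3. Leaving out differentiated replicate 1 or 2 gave adjusted p = 0.0514 and 0.0521, at log2 fold changes of -2.52 and -2.53. Leaving out differentiated replicate 3 gave 0.0512, at -2.52, with the filter applied to the other 5 libraries.

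Genes that invading cells use on the matrix also moved. Plau, which encodes urokinase, rose 8.95-fold, from 79.3 ± 5.62 to 710 ± 48.0 RPKM. Among 12 tested matrix proteases and inhibitors 8 rose, Adam15 fell, and Timp3, Mmp15 and Mmp14 did not pass (named after their values were seen; camera adjusted p = 6.25e-05, adjusted p = 0.246 with an estimated correlation). Fn1, which encodes fibronectin, rose 23.0-fold, from 19.6 ± 1.43 to 451 ± 13.1, and Lamc2, a laminin chain, from 0.465 ± 0.0299 to 3.98 ± 0.620. Of 22 integrin and basement membrane genes 12 rose, 8 fell and 2, Itga3 and Itga2 (named afterwards), did not pass (camera adjusted p = 0.0463, adjusted p = 0.386 with an estimated correlation). After scaling, 13 were higher and 4 lower, and Itga7, Itgb4, Lama5 and Sparc (named afterwards) no longer passed as lower. The list's call was lost after scaling (0.106), without stem replicate 1 on the same rows (0.0536), and in all 6 fits that left out 1 library with the filter applied to the other 5 (0.0646 to 0.102).

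Vascular and oxygen-related genes rose more often than they fell. Adm, given above, is in both the angiogenic and the hypoxia list and was the largest rise in each (log2 fold change 5.66), so their results overlap. Pgf, which encodes placental growth factor, rose from 0.977 ± 0.192 to 14.4 ± 3.01 RPKM. Of 16 tested angiogenic and vascular signalling genes, 10 rose, 4 fell (Ephb4, Efnb2, Vegfb and Ramp2) and 2 did not pass (Ramp3 and Nrp2), all 6 named after their values were seen (camera adjusted p = 0.004, adjusted p = 0.246 with an estimated correlation). Nrp2 passed as higher without stem replicate 3 (log2 fold change 0.22, adjusted p = 0.0348). Of 25 hypoxia and glycolysis genes 12 rose, 9 fell and 4 (Ndrg1, Aldoa, Egln3 and P4ha2, named afterwards) did not pass (camera adjusted p = 0.00595, adjusted p = 0.386 with an estimated correlation). Their median log2 fold change was 0.11 and their mean 0.60. After scaling, 16 of them were higher and 3 lower. The glucose transporter gene Slc2a3 fell from 98.7 ± 7.46 to 10.4 ± 1.97 RPKM.

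The next 3 lists did not pass the camera test against the other rows. Of 22 steroid and cholesterol genes 8 rose and 12 fell, with a median log2 fold change of -0.55 (-0.18 after scaling) and a mean of 0.14, and the test gave an adjusted p of 0.569. Cyp11a1, which makes the first step of steroid synthesis, rose from 1.84 ± 0.368 to 45.7 ± 10.6 RPKM, and Star, which brings cholesterol to it, from 0.525 ± 0.0503 to 14.4 ± 3.69. Of 12 labyrinth and syncytiotrophoblast genes, 2 rose (Slc16a1 and Vegfa), 9 fell and Ly6e did not pass, the 3 named after their values were seen (camera adjusted p = 0.176). Tested on its own with fry, this list fell (adjusted p = 1.29e-05). That test does not set the list against the other rows, and most tested rows changed. Dlx3, a transcription factor of that lineage, fell from 12.2 ± 1.34 to 1.01 ± 0.173, and Gjb2, a gap junction gene, from 2.68 ± 0.162 to 0.0218 ± 0.0189. Of 16 imprinted genes 8 rose, 7 fell and Zim1 (named afterwards) did not pass (camera adjusted p = 0.103), with a median of 0.58 (0.92 after scaling) and a mean of -0.15. Grb10, an adaptor of growth factor receptors, fell from 33.5 ± 2.45 to 2.01 ± 0.346.

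Markers of other cell types moved unevenly, and most of them did not reach the filter on low values. Tested were 6 of 18 endothelial and blood, 4 of 16 fibroblast and 7 of 19 pluripotent and endoderm symbols in the table. Of 6 tested endothelial and blood markers, 4 rose (Esam, Csf1r, Cdh5 and Cd68), Pecam1 fell and Gata1 did not pass, with Cdh5, Cd68, Pecam1 and Gata1 named after their values were seen (camera adjusted p = 0.0163, adjusted p = 0.246 with an estimated correlation, and 0.0861 with no filter on low values). After scaling Pecam1 no longer passed (log2 fold change -0.12, adjusted p = 0.288), so 4 were higher and none lower. The list's call was lost without each of the 3 differentiated libraries when the filter was applied to the other 5 (0.0861 to 0.108). That filter drops rows present only in the shortened group. On the rows of the fit to all 6 libraries, no fit that left out 1 library lost this call. Esam, an endothelial adhesion gene, rose from 2.78 ± 0.401 to 53.0 ± 2.48 RPKM, and Csf1r, of the macrophage lineage, from 0.554 ± 0.0819 to 4.78 ± 0.907. Of 4 tested fibroblast markers 2 rose (Pdgfra and Tagln), Pdgfrb fell and Col5a1 did not pass (camera adjusted p = 0.304; Tagln and Col5a1 named afterwards). Tagln had an adjusted p = 0.051 without stem replicate 3. Pdgfra rose from 3.20 ± 0.489 to 13.2 ± 0.144, and Pdgfrb fell from 1.51 ± 0.0161 to 0.797 ± 0.0223. Of 7 pluripotent and endoderm markers 4 rose (Pdgfra, Sox7, Col4a1 and Nid1), 2 fell (Dppa5 and Utf1) and Tdgf1 did not pass (camera adjusted p = 0.27; Sox7, Col4a1, Nid1, Utf1 and Tdgf1 named afterwards). Dppa5 fell from 8.33 ± 0.67 to 0.0782 ± 0.0678 RPKM. In all 17 lists the numbers of members that rose and fell, adjusted over the list alone, equalled those over all rows tested.

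**Figure D3:**
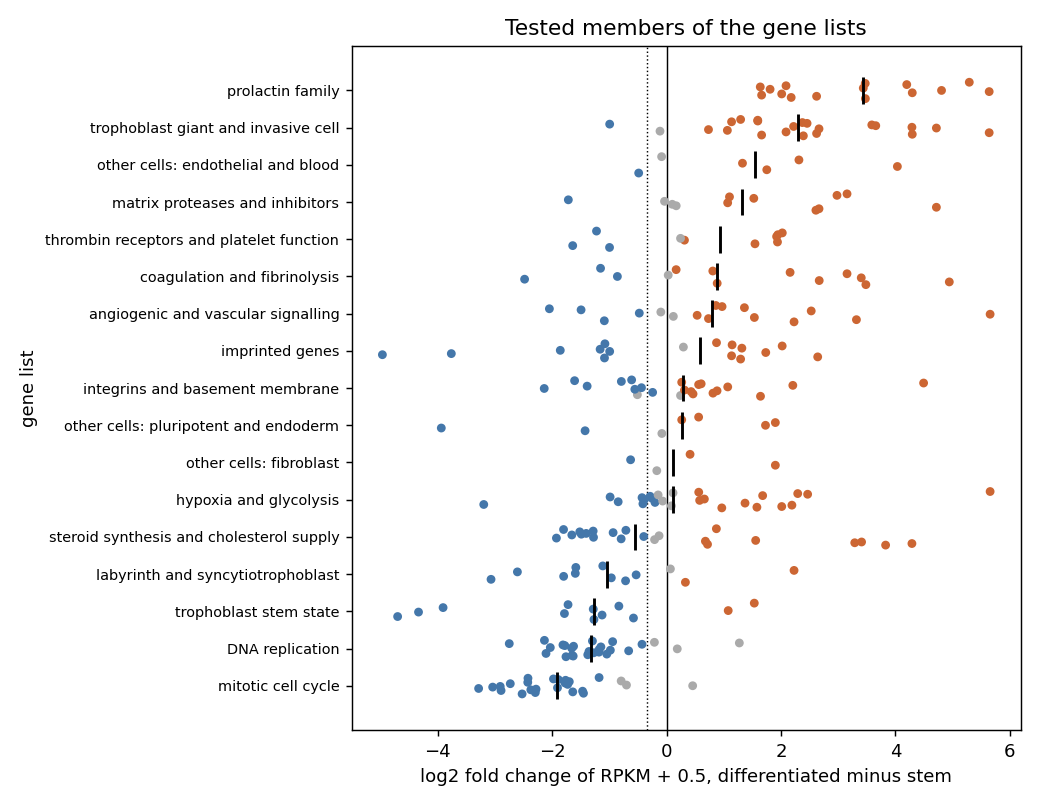
Each point is a tested member of 1 of the 17 gene lists (y axis), at its log2 fold change of RPKM + 0.5, differentiated minus stem (x axis); orange members rose, blue fell and grey did not pass an adjusted p of 0.05. Thick black ticks are list medians, and the dotted line is the median of all tested rows, -0.33. All 15 prolactin genes lie above 0, and no mitotic gene rose.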

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

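The alternatives added after the data were seen were the lane block, RPKM summed per symbol, totals without mitochondrially encoded reads, shares of reads, and, when 1 library was left out, the rows of the fit to all 6 and a filter at 2 of the 5 libraries. The filter at 3 of the 5 libraries came first. Over all alternatives the count of changed rows ran from 6617 to 10588 and that of rows changed by at least 2-fold from 2623 to 4066. The split between higher and lower rows moved most with scaling. Median-of-ratios scaling gave 4219 higher and 4202 lower rows, and at 2-fold 1800 higher and 1378 lower. Trimmed mean scaling without the prolactin family and the 10 most abundant rows gave 4200 higher and 4287 lower rows, with 1398 lower at 2-fold. With each library left out in turn on the same rows, 243 to 552 of the 8709 calls were lost and none changed sign. The replicate numbers were set as a replicate block, which gave 8593 changed rows. The deviations of same-numbered libraries correlated at -0.0041, 0.0158 and -0.0239. No pairing by number was seen, but with 3 libraries per group these values cannot exclude a shared culture. No stem library correlated best with the differentiated library of its own number. The lane block gave 8625 changed rows, and the deviations of same-lane libraries correlated at 0.0106, 0.0158 and 0.0347.

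The stem state list passed under some settings and not under others. Its adjusted p was 0.0119 with median-of-ratios scaling and 1.82e-05 with fry, but 0.0581 with voom weights, 0.0846 with at least 10 CPM in 3 libraries, 0.0664 with the replicate block, 0.0675 with RPKM summed per symbol, 0.0525 without mitochondrially encoded reads in the totals and 0.0344 to 0.0905 with 1 library left out, a range that here and below covers all 3 choices of rows tried for such fits. With the filter at 3 of the 5 libraries, its call was lost in 6 of 6 such fits, that of the integrin list in 6, that of the thrombin list in 5 and that of the endothelial and blood list in 3. On the rows of the fit to all 6 it was lost in 2, 1, 0 and 0. For the thrombin and platelet list it was 0.123 with median-of-ratios and 0.118 with trimmed mean scaling, 0.194 with at least 10 CPM, and 0.0252 to 0.157 with 1 library left out. For integrins it was 0.106 and 0.108 with the scalings, 0.0571 with RPKM summed per symbol and 0.0237 to 0.102 with 1 library left out. For endothelial and blood markers it was 0.0861 with no filter on low values and 0.0111 to 0.108 with 1 library left out. With an estimated correlation, adjusted p was 0.386 for the stem state, integrin and hypoxia lists, 0.0954 for the prolactin family, 0.109 for coagulation, and 0.246 for the thrombin, protease, mitotic, DNA replication, angiogenic and endothelial lists. With fry, which tests a list on its own, the labyrinth list (1.29e-05, down) and the fibroblast list (0.00798, up) passed. The pluripotent and endoderm list turned down with it (0.0887). Since 77.1% of all tested rows changed, passing fry says little about any 1 list, the stem state list included. The steroid list, not called under any setting, turned down with median-of-ratios scaling (0.938), with trimmed mean scaling (0.941) and with no filter (0.757). Plat changed sign with 1 library left out, between -0.026 and 0.12 on the log2 scale, never past the threshold. The rise of the prolactin share was 0.337 percentage points as a share of reads, against 0.570 as a share of RPKM. Apart from the splits and the settings that test fewer rows or samples, the cause was not tested. Library totals alone and limma-trend on RPKM were the fit reported and gave no separate value, and the Wald test on raw counts was not run, since the table holds no raw counts. Counting error limits values under about 3 reads, which is about 0.14 RPKM in a transcript of 1 kilobase and less in a longer one.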

Other observations

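The gene groups in this and the next paragraph were chosen after the data were seen, partly for their values, so no test of a group is given. Only counts of members are given, with the values of some members that were also picked afterwards. Of 22 tested immediate early and AP-1 genes 21 rose, as many as after scaling, and Nr4a1 did not pass. Myc rose from 19.4 to 296 RPKM and Dusp1 from 15.2 to 191. All 5 tested clade B serpins rose, also after scaling, Serpinb9 among them from 93.7 to 621. Of 6 carcinoembryonic antigen and pregnancy-specific glycoprotein genes 5 rose and Ceacam1 fell, with the same counts after scaling, in a family whose copies can share reads. Of 9 cathepsins 5 rose, Ctsc fell and 3 did not pass, Ctsa, Ctsf and Cts7, against 6 higher and 1 lower after scaling.

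Of 16 DNA methylation and germline-like genes 13 fell, Dnmt3a rose, and Tet3 and Tex15 did not pass, and after scaling 11 were lower. Of 28 epithelial genes 19 fell and 9 rose, against 17 and 9 after scaling. Cdh1 fell from 72.5 to 2.78 RPKM and Cldn4 from 196 to 38.5, while Krt7 rose from 54.0 to 386 and Krt8 from 834 to 2519. Of 73 cytosolic ribosomal protein genes 9 rose and 32 fell, but after scaling 50 were higher and 9 lower. Of 56 heat shock protein and J-domain co-chaperone genes 17 rose and 30 fell, against 22 and 20 after scaling. Of 12 mitochondrially encoded genes none rose and 9 fell, against 3 and 5 after scaling.

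The tests in this and the following paragraphs were chosen after the result was seen, except the split counts and the test without the 100 most abundant rows, which were written down first. In stem replicate 3, 275 tested rows lay over 2-fold below both other stem libraries and 6 above, against at most 11 below in any other library relative to its own group. These rows were mostly not called until that library was left out, when 208 of 275 passed, 117 of them lower in differentiated cells, against 36 with it. Differentiated cells in the culture were argued against, since the median share of differentiated signal over 93 rows at least 8-fold higher in such cells was -7.49e-05 (quartiles -0.00915 and 0.0059). Fewer dividing cells were argued against as the whole cause, since the mitotic list differed by a median of 0.0413 (log2) while the low rows differed by -1.49. The mitotic list's quartiles were -0.493 and 0.15, however, and 5 of its 25 members were among the low rows. A general loss of long transcripts was argued against by Spearman's rho of 0.0306 between the difference and row length across rows, which are not independent replicates. A median difference of 0.101 over the 1130 longest of 11293 rows also argued against it. Yet 28.7% of the low rows were among those 1130, and the low rows had a median length of 3165 bases against 1989 for the other tested rows. A loss limited to some long transcripts stays open. Base composition was not tested, since no sequence was used here, and it stays open with library preparation.

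The fall of the median tested row, -0.33 on the log2 scale, was not removed by either change of the library totals. With the reads of the 100 most abundant rows left out it was -0.31, and with only reads inside the rows as totals it was -0.27. Neither is therefore the whole cause. A real concentration of expression in fewer genes stays open.

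The 2 Tfpi rows moved unequally. The row of 844 bases took 0.482% ± 0.198 of Tfpi reads in stem and 4.94% ± 0.457 in differentiated libraries (n = 3 each, exact two-sided permutation p = 0.1, the smallest possible), higher in all 3. A fixed share of reads passed from the row of 1226 bases would keep the ratio constant, but it rose 10.7-fold. Among 543 symbols with 2 rows and at least 100 reads in each, the ratio changed in 129 (limma, adjusted p under 0.05), and Tfpi had the second largest change after Prl8a9 (log2 3.14, adjusted p = 0.000771). A hypothesis is that transcript choice at Tfpi changes with differentiation, which stays untested, since the rows' exons were not used here.

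The median log2 fold change of the mitotic list minus that of the DNA replication list was -0.58, and -0.68 without stem replicate 3. A permutation over members gave p = 0.00314 (100000 permutations, genes not independent), but the comparison was chosen after the medians were seen, so it is a description of these lists. Whether cells replicated without dividing was not tested.

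With 10 splits of the 6 libraries, no share under 0.05 can be reached. The real split was the 1 split of 10 with as many changed rows, 8709, and as many at 2-fold, 3596, where the highest other split gave 0 in limma for both (at an unadjusted p under 0.05, 50 rows against 8865). The real split gave 12 gene lists past the threshold, again the 1 split with as many, but the other splits gave 5 to 11. Each other split still holds unequal numbers of stem and differentiated libraries on its sides, so such counts are not a pure measure of chance. These counts therefore cannot say how often lists are called falsely at the preset correlation. Such calls stay uncertain, and only the giant and invasive cell list held with an estimated correlation. In camera that setting also takes its degrees of freedom from the residuals of the 6 libraries, far fewer than with a preset correlation. Lost calls therefore do not measure correlation of members alone. Correlation of members was not the only reason, since the coagulation and thrombin lists were lost at estimated correlations of -0.05 and 0.00721, under the preset 0.01.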
